A study of Mus musculus with 8 samples.

How the data were processed

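RNA was measured by sequencing in 8 libraries from wild-type mouse bone marrow, 4 of Ly6C+ classical monocytes and 4 of common monocyte progenitors (cMoPs), the proliferating precursors of monocytes. Sorted cells of each kind had been cocultured for 6 h with OP9 cells, a mouse bone marrow stromal line, or with OP9-DLL1 cells, the same line made to display the Notch ligand DLL1, which gives 4 groups of 2 libraries. Per the labels' protocols, libraries were made with a SMARTer Ultra Low kit and sequenced as read pairs of 150 bases. This kind of kit does not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

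Per the submitters' processing notes, the tools used were bcl2fastq, STAR 2.7.9a, Subread, featureCounts 2.0.3, Salmon 1.5.2, edgeR and limma, with genome build mm10. Their order, the annotation release, the gene filter and the model are not given in the sources used here. The deposited table has 13430 entries for 13388 gene identifiers, of which 42 entries repeat an identifier and were dropped, keeping the first entry of each identifier. Its sample columns hold log2 CPM, reads scaled to a common library size, normalized by the authors with an effective size for each library. The authors' deposited table also holds their own log2 fold changes and p-values for 4 comparisons. Those were given as OP9 minus OP9-DLL1 for the coculture contrasts and were turned here, so that positive values mean higher on OP9-DLL1.

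The deposited log2 values had the form limma's voom writes, with 0.5 reads added to each count. Taking the lowest value of each column as 0 reads gave whole reads for 100.0% of values in every library (tolerance 0.001), and the effective library size with them. Recovered totals served as the measure of depth and for intervals, not for the main test. At these depths 1 read corresponded to 0.0151 to 0.0231 CPM. For a gene with 0 reads in both libraries of a group, a floor of 3 counts over the group was used and the fold is given as a lower bound. For 1 to 3 reads the ratio of summed reads is given with its 95% counting interval (exact binomial). Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Gene positions and gene types are from GENCODE mouse release M21 on GRCm38, the assembly that mm10 denotes, in which 13380 of the 13388 identifiers were found.

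The test was limma-trend (limma 3.58.1 in R 4.3.3) on the deposited log2 values, with 1 mean per group over all 8 libraries (4 residual degrees of freedom) and genes at 1 CPM or more in at least 2 libraries (13374 genes, 14 left out). Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 are said to pass. The contrasts tested in that fit were OP9-DLL1 against OP9 in each cell type, the difference of those responses, and cMoPs against monocytes on each stroma. Values are CPM as mean ± SD (n = 2 libraries) and log2 fold changes ± SE. The labels number the replicates without saying that they came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Replicates differed by more than counting noise in every group (chi-square per degree of freedom 24.2 to 158.2), so none was a library deposited again.

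The model, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Named genes are, among genes that passed with both libraries of 1 group above both of the other and a mean of at least 5 CPM in the higher group, the 10 highest and 10 lowest by log2 fold change without predicted gene models. Bcl6, Irf2, Notch1, Notch2, Dll1, Nr4a1, Hes1, Nrarp, Dtx1 and Ly6c2 were added whatever their result, as were up to 4 members of each fixed list by adjusted p, or up to 2 given as values where none passed. For the difference of responses the 5 highest and 5 lowest were taken. Dll1, Nrarp and Dtx1 are not analysed here. Members behind a list count of 5 or fewer that stand outside this rule were named after their values were seen, and the text says so for each. A few genes that the rule or a small count would name are not reported here. Neighbouring or near-identical family members, such as Ly6c2 and Ly6c1, Ccl2, Ccl7 and Ccl12, and the class II genes, may share reads, and their values are uncertain to that extent.

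24 gene lists were fixed, and the 20 with at least 5 tested members were tested with limma's camera (preset correlation 0.01), which compares a list with all other genes, and with Benjamini-Hochberg adjustment over lists. Camera was also run with the correlation estimated per list, and fry, which tests whether a list's genes move on balance in 1 direction, was run beside it. With an estimated correlation no list passed in any comparison, so that adjusted p is given beside the camera result of each list that the text describes as called. Lists lost the call there even at an estimated correlation below the preset 0.01. The immediate early list in cMoPs against monocytes on OP9, at 0.002, went from a camera adjusted p of 4e-06 to 0.088. Losing the call therefore does not by itself show that correlation within a list accounts for it.

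The procedure was tested on simulated data drawn for the 13374 genes, 10 runs per coculture contrast with 100 genes changed 2-fold and 100 changed 4-fold. Changed genes were drawn only from those with a mean log2 CPM above 2 over the groups. The recovery below therefore does not cover genes nearer the floor. In the monocyte contrast a median of 73.5% of 2-fold and 99.5% of 4-fold changes passed, with a median of 12 false calls. In the cMoP contrast these were 71.0%, 99.5% and 8.5. With no gene changed the median number of calls was 0 in both contrasts, and the highest was 1. A shifted list was called in 10 of 10 runs of the monocyte contrast, with 0 other list calls. Each simulated gene was drawn independently, with 1 spread for all 8 libraries. In the data the residual SD was 0.531 in OP9 monocytes and 0.396 to 0.428 in the other groups. The estimated correlation within the cell cycle list was 0.651. The low numbers of false gene and list calls hold only under the simulated assumptions.

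Alternatives were a replicate block, centring of each library on its median, limma without the mean-variance trend, pseudocounts of 0.1 and 5 CPM, no filter, a filter of 10 CPM, a fit of only the 4 libraries compared, a log2 fold change of at least 1, and leaving out each library in turn. Limma-voom and limma-voom with library weights on the recovered reads were added after the data had been examined. A count model on the recovered reads had been planned and was not run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.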

Results

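The series measured gene expression in Ly6C+ classical monocytes and in cMoPs after 6 h on OP9 or OP9-DLL1 stroma, with 2 libraries in each of the 4 groups. Its title names Bcl6, Irf2 and Notch2 as promoting the development of nonclassical monocytes, and the design asks what contact with a Notch ligand changes in each cell type. Recovered depth was 47316323 and 54282613 reads for monocytes on OP9, 51237246 and 52302602 for monocytes on OP9-DLL1, 62459962 and 51566715 for cMoPs on OP9, and 55868453 and 57732330 for cMoPs on OP9-DLL1. The OP9 monocyte libraries differed most from each other, with 1445 genes more than 2-fold apart, against 724 to 804 genes in the other groups.

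In monocytes, the Notch target Hes1, a transcriptional repressor (chromosome 16, 30064384 to 30067796), rose from 0.041 ± 0.008 to 11.5 ± 0.3 CPM on OP9-DLL1 (SD, n = 2), which is 3 against 1151 reads and a ratio of 372 (95% counting interval 127 to 1800). Spic, an ETS factor of red pulp macrophages (chromosome 10, 88674772 to 88685015), rose from 1.73 ± 0.436 to 120.4 ± 5.73 CPM (log2 6.15 ± 0.32, SE). Itgax, which encodes the integrin CD11c (chromosome 7, 128129547 to 128150657), rose from 1.33 ± 0.159 to 25.4 ± 3.73 CPM (log2 4.25 ± 0.37). The chemokine genes Ccl2, Ccl7 and Ccl12, whose products recruit CCR2-bearing cells, fell. Ccl2 (chromosome 11, 82035571 to 82037453) fell from 1390.0 ± 426.7 to 47.0 ± 14.1 CPM (log2 -4.89 ± 0.26). Their limma-trend adjusted p-values lay between 4.8e-05 for Ccl2 and Spic and 0.0021 for Ccl12.

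Other genes with large rises in monocytes on OP9-DLL1 were Ocstamp, a fusion protein of osteoclasts (log2 5.85 ± 0.36), the inhibitory lectin Cd22 (5.24 ± 0.45), the efflux transporter Abcb1a (5.10 ± 0.58), the short-chain fatty acid receptor Ffar2 (4.53 ± 0.55) and Abcg3 (4.41 ± 0.57). Dnase1l3 (7.10 ± 1.39) and Adgrg5 (5.42 ± 1.15) also passed. Large falls beside the chemokines were in Lpl, lipoprotein lipase (-3.03 ± 0.31), and Spp1, osteopontin (-2.99 ± 0.18), from 2202 ± 601 to 273 ± 10.8 CPM. Ccl12 had 721 reads on OP9 and 2 on OP9-DLL1 (ratio 372, interval 103 to 3080), and Ccl7 had a log2 fold change of -6.94 ± 0.52. Pdpn, Cxcl2, Ppbp, Pf4 and Stab1 fell with log2 fold changes from -3.80 to -3.02. Without OP9-DLL1 monocyte replicate 2 the calls of Dnase1l3, Adgrg5, Pdpn, Cxcl2, Ppbp, Pf4 and Stab1 ended, and their highest adjusted p with 1 library left out ranged from 0.0539 for Pf4 to 0.28 for Pdpn. Dnase1l3, Adgrg5, Pdpn and Ppbp also lost the call without OP9-DLL1 replicate 1, and Ppbp without either OP9 library.

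**Figure D1:**
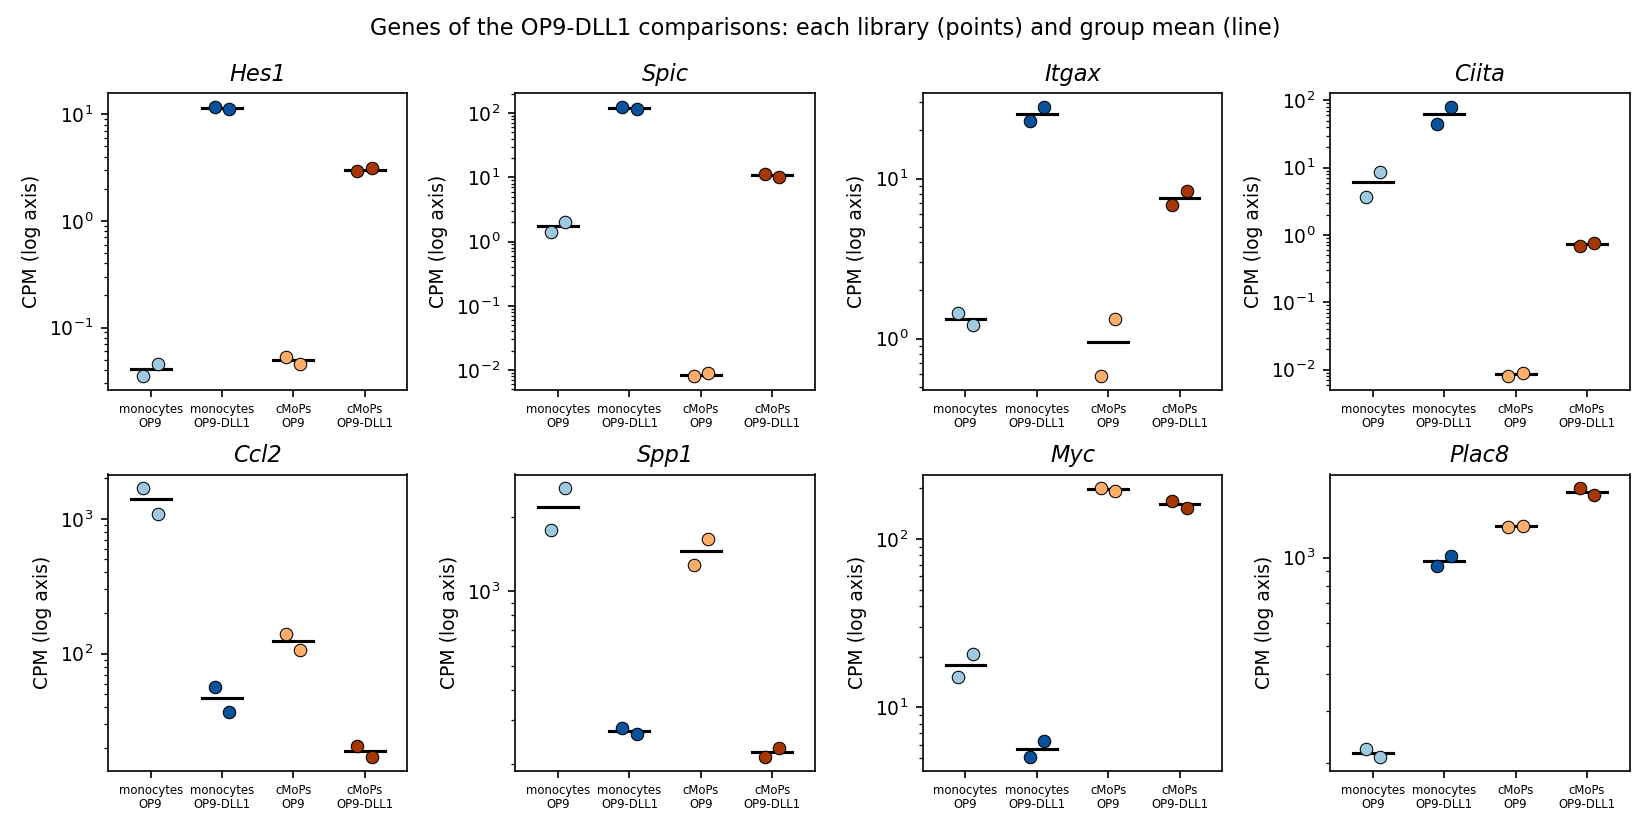
CPM (log axis) of 8 genes in each of the 8 libraries (points) with the group mean (line), for monocytes and cMoPs on OP9 or OP9-DLL1, with 0 reads drawn at the 0.5 reads added to every count. Hes1, Spic and Itgax stand higher and Ccl2 and Spp1 lower on OP9-DLL1 in both cell types.

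The genes in the title of the series did not pass in monocytes. Bcl6 was at 6.06 ± 1.92 CPM on OP9 and 7.46 ± 1.43 CPM on OP9-DLL1 (log2 0.33 ± 0.60, adjusted p = 0.8), Irf2 at 198 ± 36.3 and 182 ± 17.5 CPM (-0.11 ± 0.16, adjusted p = 0.73) and Notch2 at 65.4 ± 7.29 and 71.2 ± 5.50 CPM (0.13 ± 0.16, adjusted p = 0.7). Neither did Notch1 (-0.17 ± 0.18), Nr4a1, a nuclear receptor needed for nonclassical monocytes (0.87 ± 0.41, adjusted p = 0.25), or the classical monocyte marker Ly6c2 (0.06 ± 0.16).

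Of 28 tested genes of the nonclassical monocyte list, 11 rose and 0 fell (limma-trend, with 3 lower at an unadjusted p under 0.05, 2 lower by voom and 1 lower by weighted voom), or 13 and 2 adjusted over the list alone. Members that rose include Itgax, the integrin Itgal (log2 2.40 ± 0.20), the inhibitory receptor Lair1 (1.24 ± 0.13) and the transglutaminase Tgm2 (2.50 ± 0.36). The list median was 0.75 (camera adjusted p = 9.5e-06, but adjusted p = 0.13 with an estimated correlation). Of 11 class II antigen presentation genes 7 rose and 0 fell (0 lower at an unadjusted p under 0.05 and by both voom fits), or 9 adjusted over the list alone. They include the class II transactivator Ciita (3.40 ± 0.52), H2-Ab1 (2.50 ± 0.37), H2-DMb1 (1.04 ± 0.20) and H2-DMa (0.85 ± 0.16). The class II median was 1.22 (camera adjusted p = 2.2e-08, but adjusted p = 0.13 with an estimated correlation). Between the libraries of this comparison the class II median was 5.48 and 6.65 log2 CPM on OP9 and 7.60 and 8.24 on OP9-DLL1. Tgm2, Ciita, H2-DMa and H2-DMb1 lost the call without OP9-DLL1 monocyte replicate 2 (adjusted p at most 0.0546, 0.123, 0.119 and 0.102 with 1 library left out).

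Of 25 ribosome biogenesis genes 16 fell and 0 rose in monocytes (0 higher at an unadjusted p under 0.05 and by both voom fits), or 22 adjusted over the list alone. The nucleolar genes Gnl3 (log2 -1.44 ± 0.15), Wdr43 (-1.03 ± 0.13) and Nop58 (-1.12 ± 0.16) fell, as did the polyamine synthesis gene Odc1 (-1.30 ± 0.18). The list median was -0.76 (camera adjusted p = 6.2e-19, but adjusted p = 0.095 with an estimated correlation). Nop58 lost the call without OP9-DLL1 replicate 2 (adjusted p at most 0.057). Of 20 cholesterol biosynthesis genes 3 rose and 0 fell (0 lower at an unadjusted p under 0.05 and by both voom fits), 11 adjusted over the list alone, with Mvd at 0.64 ± 0.14, Fdft1 at 0.71 ± 0.18 and Acat2 at 0.55 ± 0.13 (camera adjusted p = 5.4e-08, but adjusted p = 0.34 with an estimated correlation). Mvd, Fdft1 and Acat2 each lost the call without either OP9-DLL1 library (adjusted p at most 0.185, 0.248 and 0.291), and Fdft1 without OP9 replicate 1 as well. In the glycolysis and hypoxia list 2 of 22 genes fell, P4ha1 (-0.57 ± 0.13) and Pdk1 (-1.67 ± 0.42, named after its value was seen), and Car9 rose (3.39 ± 0.402 to 6.75 ± 0.622 CPM), with 1 and 5 adjusted over the list alone for higher and lower (camera adjusted p = 0.00044, but adjusted p = 0.17 with an estimated correlation). In the immediate early list Egr1 (-2.53 ± 0.38) and Fos (-0.70 ± 0.15) fell and the phosphatase Dusp2 (2.01 ± 0.35) rose among 22 genes (camera adjusted p = 0.033, but adjusted p = 0.21 with an estimated correlation). By weighted voom 11 nonclassical, 6 class II and 1 cholesterol genes rose (13, 9 and 4 by voom). Ribosome biogenesis had 11 lower (16 by voom). Weighted voom called 0 higher and 0 lower in the glycolysis and hypoxia list (1 and 3 by voom), and 1 and 3 in the immediate early list (2 and 4 by voom). Without 1 OP9-DLL1 library Car9, P4ha1, Dusp2 and Fos no longer passed (adjusted p at most 0.144, 0.257, 0.108 and 0.229), nor did Fos and Pdk1 without OP9 replicate 1 (Pdk1 at most 0.153). Of 38 cell cycle genes 0 rose and 0 fell by limma-trend (2 higher and 0 lower at an unadjusted p under 0.05, 0 by both voom fits), and the list's median of 0.28 passed by camera (adjusted p = 0.01, but adjusted p = 0.93 with an estimated correlation). The cell cycle median was 5.28 and 6.11 log2 CPM in the OP9 monocyte libraries and 5.94 and 6.08 in those on OP9-DLL1.

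Other lists did not pass in monocytes. Of 22 listed Notch target genes only 10 were tested, and Hes5, Hey1, Hey2, Heyl and Notch3 are among those that were not. Of the 10, Hes1 rose and Myc (log2 -1.65 ± 0.18) was 1 of 2 that fell. The other was the cyclin gene Ccnd1 (-1.85 ± 0.35). Each voom fit called 1 lower, and in the authors' deposited table the adjusted p was 0.0032 for Myc and 0.082 for Ccnd1. That list's median was -0.14, its mean 0.55, and camera gave a fall (adjusted p = 0.92) and fry a rise (adjusted p = 0.0025, but camera adjusted p = 0.98 with an estimated correlation), so these measures differ in sign. Among its members 4 had positive log2 fold changes, with Hes1 the largest at 8.16, and 6 had negative ones. Of 20 Notch pathway components Rbpj, the DNA-binding partner of Notch, fell from 69.5 ± 3.93 to 27.2 ± 4.01 CPM (-1.36 ± 0.17), and the glycosyltransferase Mfng rose (1.04 ± 0.20, not without either OP9-DLL1 library, adjusted p at most 0.143). Of 21 classical monocyte genes 2 rose, Plac8 (2.18 ± 0.10) and glutathione reductase Gsr (0.97 ± 0.11), and 4 fell, fibronectin Fn1 (-1.30 ± 0.16), the Fc receptor Fcgr1 (-1.62 ± 0.25), F13a1 (-0.68 ± 0.14) and Clec4e (-0.56 ± 0.13). Of 29 monocyte transcription factors 6 rose and 3 fell, with Irf1 at 1.32 ± 0.14, Runx3 at 1.85 ± 0.22 and Irf8 at 1.53 ± 0.22 among the former and Egr1 and Maf (-1.41 ± 0.28) among the latter. Of 24 NF-kB and inflammatory genes 3 rose and 4 fell, with Tnfaip2 at 0.96 ± 0.11, Icam1 at 1.06 ± 0.18 and Nfkb2 from 16.6 to 33.4 CPM, against Ccl2, Ccl7, Cxcl2 and Ccl3 (-1.01 ± 0.19). That list's median was 0.17 and its mean -0.56, so they differ in sign too. Of 26 interferon response genes Gbp2 rose (1.23 ± 0.31) and Usp18 fell (-0.92 ± 0.22), and of 21 progenitor genes Ms4a3 (2.24 ± 0.24), Irf8 and Igsf6 (0.54 ± 0.13) rose and Clec12a fell (-1.06 ± 0.19). Weighted voom called 0 interferon genes higher and 2 lower (2 and 2 by voom), and 2 progenitor genes higher and 1 lower (3 and 1 by voom). Calls that ended without OP9-DLL1 monocyte replicate 2 were those of Fcgr1, Irf8, Gbp2, Usp18, Clec12a, Igsf6, Ccnd1, F13a1, Clec4e, Maf, Nfkb2 and Ccl3, and that of Icam1 ended without replicate 1. Their adjusted p with 1 library left out was at most 0.0723, 0.0539, 0.245, 0.271, 0.108, 0.248, 0.102, 0.185, 0.259, 0.178, 0.211, 0.145 and 0.0855 in that order. Ccnd1, F13a1, Clec4e, Maf, Nfkb2 and Ccl3 are named here because so few genes passed, chosen after their values were seen.

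Markers of other cell types were also measured. The 11 stroma genes other than Acta2 and Thbs1, which myeloid cells express too, summed to 44.6 and 39.4 CPM in monocytes on OP9, 7.40 and 26.6 CPM in monocytes on OP9-DLL1, and 3.92 to 7.26 CPM in cMoPs. Of all 13 tested stroma genes the receptor gene Pdgfrb rose (log2 5.35 ± 0.93) and 0 fell in monocytes (2 lower at an unadjusted p under 0.05, 2 by voom and 1 by weighted voom). Voom called 1 stroma gene higher and weighted voom 0. The platelet chemokines Pf4 and Ppbp, the 2 tested megakaryocyte genes, fell. Of 15 macrophage genes 1 rose, Spic, and 2 fell, Cd163 (-2.73 ± 0.46) and Trem2 (-0.80 ± 0.16). Of 8 dendritic cell genes Batf3 (3.03 ± 0.66) and Mgl2 (2.79 ± 0.53) rose, of 13 neutrophil genes 1 rose, Csf3r (115 ± 21.1 to 229 ± 12.3 CPM, not without OP9-DLL1 replicate 2, adjusted p at most 0.0789), and of 5 mast cell, basophil and eosinophil genes 1 rose, histidine decarboxylase Hdc (1.83 ± 0.20). None of the 2 erythroid, 1 T and NK cell, 3 B cell and 13 mitochondrially encoded genes passed (limma-trend), with Car2 at 1.34 ± 0.39, Lck at -1.37 ± 0.78, Cd79b at 0.41 ± 0.18 and mt-Co1 at 0.31 ± 0.15. Cd163, Trem2 and Mgl2 lost the call without OP9-DLL1 replicate 2 (adjusted p at most 0.0756, 0.12 and 0.106), and Pdgfrb, Cd163, Batf3 and Mgl2 were chosen for naming after their values were seen. At an unadjusted p under 0.05 these lists held 1, 0, 1 and 0 genes, and both voom fits called 0. Among dendritic cell genes each voom fit called 1 higher. In the authors' deposited table Mgl2 (adjusted p = 0.41) and Pdgfrb (0.073) did not pass. Batf3, Cd163, Trem2, Csf3r and Hdc passed there.

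In all, 855 of 13374 genes passed in monocytes, 450 higher and 405 lower on OP9-DLL1 (52.6% higher). With libraries centred on their medians the count was 906, of which 39.8% were higher. The authors' deposited table calls 573 genes, 514 of them also called here in the same direction. The count was 278 without OP9-DLL1 replicate 1, 162 without OP9-DLL1 replicate 2 and 2482 without OP9 replicate 2. It was 248 without the mean-variance trend, 306 with only these 4 libraries and 536 by weighted voom, and 27 of the 59 named genes that passed did so under every setting.

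In cMoPs on OP9-DLL1, Spic rose from 0 reads to 10.7 ± 0.973 CPM (SD, n = 2), at least 432-fold over a floor of 3 counts in the group (limma-trend adjusted p = 1.3e-06). Cd22 rose from 0.177 ± 0.047 to 7.41 ± 1.54 CPM (log2 5.40 ± 0.45) and Pla2g7, a phospholipase that breaks down platelet-activating factor, from 3.87 ± 0.561 to 66.9 ± 13.3 CPM (4.11 ± 0.25). Hes1 rose from 0.049 ± 0.005 to 3.03 ± 0.146 CPM (5.94 ± 0.58, adjusted p = 0.0015), and the decoy receptor Il1r2 rose from 3.93 ± 1.38 to 29.0 ± 7.22 CPM (2.91 ± 0.26). Spp1 fell from 1456 ± 252 to 223 ± 14.2 CPM (-2.70 ± 0.18) and Ccl2 from 124 ± 23.8 to 19.0 ± 2.65 CPM (-2.70 ± 0.26). The chemokine Ccl4 (-2.70 ± 0.28) and the metalloprotease Adam8 (-1.53 ± 0.12) fell too.

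The adhesion molecules F11r (log2 3.86 ± 0.34) and Jaml (2.97 ± 0.24) rose, and Pid1 (-2.56 ± 0.24) and the zinc transporter Slc39a14 (-1.98 ± 0.18) fell. Itgax (3.11 ± 0.37), Stra6l (3.93 ± 0.54), Abcg3 (3.56 ± 0.57) and Ocstamp (2.58 ± 0.36) rose, and Pcdh7 (-4.16 ± 0.67), Lpl (-2.77 ± 0.31), Dab2 (-1.54 ± 0.23) and C5ar1 (-1.59 ± 0.25) fell. These 8 calls each ended without at least 1 cMoP library, with adjusted p at most 0.07, 0.135, 0.221, 0.121, 0.236, 0.0535, 0.169 and 0.189 in that order. Itgax lost it without OP9-DLL1 replicate 2, Lpl without OP9 replicate 2, and Ocstamp without any but OP9 replicate 1. Stra6l, Abcg3 and Pcdh7 lost it without any of the 4, C5ar1 without any but OP9-DLL1 replicate 2, and Dab2 without any but OP9-DLL1 replicate 1. In the authors' deposited table C5ar1 did not pass (adjusted p = 0.11), and the others of these 8 did. Bcl6 (-1.11 ± 0.60), Irf2 (-0.17 ± 0.16), Notch1 (-0.11 ± 0.18), Notch2 (-0.20 ± 0.16) and Nr4a1 (1.96 ± 0.41, adjusted p = 0.08) did not pass, and Ly6c2 was at 2193 ± 170 and 2189 ± 176 CPM.

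Of 24 NF-kB and inflammatory genes 4 fell and 0 rose in cMoPs (3 higher at an unadjusted p under 0.05, 0 by both voom fits), or 7 and 2 adjusted over the list alone, namely Ccl2, Ccl4, Ccl3 (log2 -1.14 ± 0.19) and Ccl7 (-3.35 ± 0.52). Camera gave adjusted p = 0.014, but adjusted p = 0.55 with an estimated correlation. Of 21 classical monocyte genes 2 fell, the chemokine receptor Ccr2 (-0.86 ± 0.12) and versican Vcan (-1.38 ± 0.20), and of 26 interferon response genes Irf7 rose (1.76 ± 0.25). Ccl3, Ccr2, Vcan and Irf7 lost the call without any 1 of the 4 cMoP libraries (adjusted p at most 0.293, 0.172, 0.158 and 0.164). Of the nonclassical list Itgax and Ear2 (2.41 ± 0.35) of 28 genes rose and Fabp4 fell (42 to 0 reads, at least 13.5-fold), and of the class II list Ciita of 11 rose (0 to 84 reads, at least 29.1-fold). Voom called 0 class II genes higher, so Ciita did not pass there, and weighted voom called 2. In the authors' deposited table the adjusted p of Ciita was 0.098. Of the 10 tested Notch target genes Hes1 rose and Snai1 fell (17 to 0 reads, at least 5.44-fold), of 29 transcription factors Maf fell (-2.03 ± 0.28), and of 15 macrophage genes Spic rose. By voom 2 NF-kB genes, 1 classical gene and 0 transcription factors were lower. Interferon genes had 0 higher by voom, and nonclassical genes 1 higher and 0 lower. Irf7, Maf and Fabp4 therefore did not pass by voom. Weighted voom gave 4, 3, 3, 3, 7 and 0 in that order. In the authors' deposited table Ccl7 (adjusted p = 0.23), Snai1 (0.2), Maf (0.08), Ear2 (0.066) and Fabp4 (0.062) did not pass either. Ccl2, Ccl4, Ccl3, Ccr2, Vcan, Irf7, Itgax, Hes1 and Spic passed there. Ear2, Fabp4, Ciita, Snai1, Maf and Ccl7 were chosen for naming after their values were seen, and all but Ciita lost the call without OP9 replicate 2 or OP9-DLL1 replicate 1 (adjusted p at most 0.119 for Ear2, 0.271 for Fabp4, 0.241 for Snai1, 0.113 for Maf and 0.213 for Ccl7). The interferon (camera adjusted p = 0.0084, but adjusted p = 0.49 with an estimated correlation), nonclassical (0.019 and 0.47), class II (0.00028 and 0.47), cholesterol (7.2e-06 and 0.47) and cell cycle (0.045 and 0.72) lists stood higher by camera. Ribosome biogenesis (0.00028 and 0.47), transcription factors (0.01 and 0.47) and mitochondrially encoded genes (0.019 and 0.66) stood lower. Interferon medians of cMoP replicates 1 and 2 were 1.72 and 1.06 log2 CPM on OP9, and 1.90 and 1.90 on OP9-DLL1. Nonclassical medians were 2.44 and 1.51 on OP9, and 2.91 and 2.80 on OP9-DLL1. On both lists OP9 replicate 2 stood lowest and contributed much of the rise. In the ribosome list 0 of 25 genes passed (4 lower at an unadjusted p under 0.05, 3 by weighted voom and 0 by voom), with Nolc1 at -0.41 ± 0.13. In the cholesterol list 0 of 20 passed (8 higher at an unadjusted p under 0.05, 2 by weighted voom and 0 by voom), with Sc5d at 0.48 ± 0.13. Among neutrophil genes 0 of 13 passed (limma-trend, 3 higher at an unadjusted p under 0.05, 1 by each voom fit), with Cxcr2 at 1.76 ± 0.33 (adjusted p = 0.053).

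In all, 103 genes passed in cMoPs, 62 higher and 41 lower, and the authors' deposited table calls 244, of which 92 are shared in the same direction. The count was 48 and 31 without OP9 replicate 1 and 2, and 49 and 39 without OP9-DLL1 replicate 1 and 2. It was 37 without the trend, 64 by voom, 268 by weighted voom and 315 with only these 4 libraries. The main fit gave each gene the same standard error in both cell types, from the spread of all 8 libraries. The residual SD was 0.531 in OP9 monocytes and 0.396 and 0.428 in the cMoP groups. With only the 4 libraries compared, 306 genes passed in monocytes and 315 in cMoPs. The counts of 855 and 103 therefore do not rank the responses of the cell types.

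Across genes, the responses of both cell types to OP9-DLL1 were positively related (Pearson r = 0.396, Spearman rho = 0.312, covariance 0.149). The fold changes share no library, and genes are not independent replicates. 45 genes rose in both, where independent lists would share 2.09, and 27 fell in both, against 1.24. Both tests used the same variance per gene, from all 8 libraries, so genes of low variance pass more easily in both. The numbers for independent lists are therefore too low a baseline. Hes1, Spic, Cd22, Itgax, Ocstamp and Abcg3 are among those that rose in both, and Ccl2, Spp1 and Lpl among those that fell. No gene passed in opposite directions. Of the 855 genes that passed in monocytes 735 had the same sign in cMoPs (86%), with a median absolute log2 fold change of 0.96 in monocytes and 0.32 in cMoPs. Of the 103 that passed in cMoPs 99 had the same sign in monocytes, with medians of 1.54 in cMoPs and 1.13 in monocytes. Each set was selected for passing in its own cell type, which raises its median there, so these medians rank neither response above the other.

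**Figure D2:**
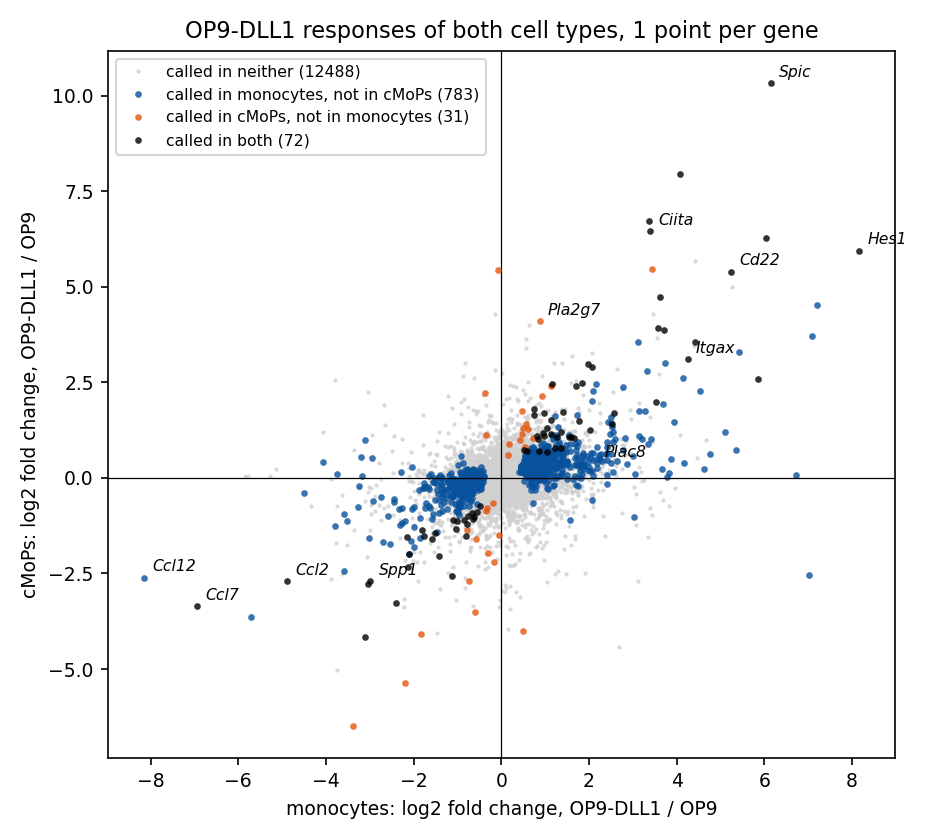
Log2 fold change on OP9-DLL1 against OP9 in monocytes (horizontal axis) and in cMoPs (vertical axis), 1 point per tested gene, coloured by the cell type in which the gene passed. The 72 genes that passed in both lie in the quadrants of equal sign, and Hes1, Spic and Cd22 stand far out on the higher side.

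The difference of the responses was tested directly and passed for 7 genes. The response in cMoPs exceeded that in monocytes for Pla2g7 (log2 difference 3.23 ± 0.35), Gpatch4 (1.54 ± 0.19), the chromatin protein Hmga1 (1.34 ± 0.15) and Spic. With 0 reads of Spic in cMoPs on OP9, its fitted difference of 4.19 rests on the 0.5 reads added to each count. The cMoP fold over the floor of 3 counts (log2 8.75) minus the fitted monocyte fold (6.15 ± 0.32) was 2.60. That value carries the error of the monocyte fold and is not a strict lower bound. The response in cMoPs was below that in monocytes for the adhesion molecule Pecam1 (-2.33 ± 0.21), the cytokine receptor Il21r (-1.92 ± 0.23) and Plac8 (-1.78 ± 0.14). Limma-trend adjusted p-values ran from 0.0052 for Plac8 to 0.03 for Gpatch4 and Il21r. The count was 29 and 1123 without OP9 monocyte replicate 1 and 2, and 0 without any 1 of the other 6 libraries (limma-trend, 787 to 1073 genes at an unadjusted p under 0.05). With all libraries it was 6 by voom and 9 by weighted voom, 1 without the trend and 60 with 5 CPM added. Spic's difference turned to -2.57 with 5 CPM added.

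Among the fixed lists, ribosome biogenesis had the smallest camera adjusted p for the difference of responses. It stood higher, with a median of 0.54 (camera adjusted p = 1.5e-14, but adjusted p = 0.15 with an estimated correlation). Of its 25 genes 0 passed (limma-trend, 15 higher at an unadjusted p under 0.05, 0 by both voom fits), or 12 adjusted over the list alone. Macrophage genes (camera adjusted p = 0.0031, but adjusted p = 0.34 with an estimated correlation), glycolysis and hypoxia (0.01 and 0.35), interferon response (0.03 and 0.51) and stroma genes (0.047 and 0.52) also stood higher. Nonclassical genes (0.0031 and 0.34), transcription factors (0.0031 and 0.35), mitochondrially encoded (0.0031 and 0.53), class II (0.0068 and 0.35) and cholesterol genes (0.047 and 0.65) stood lower. Spic and Plac8 were the only list members that passed.

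**Figure D3:**
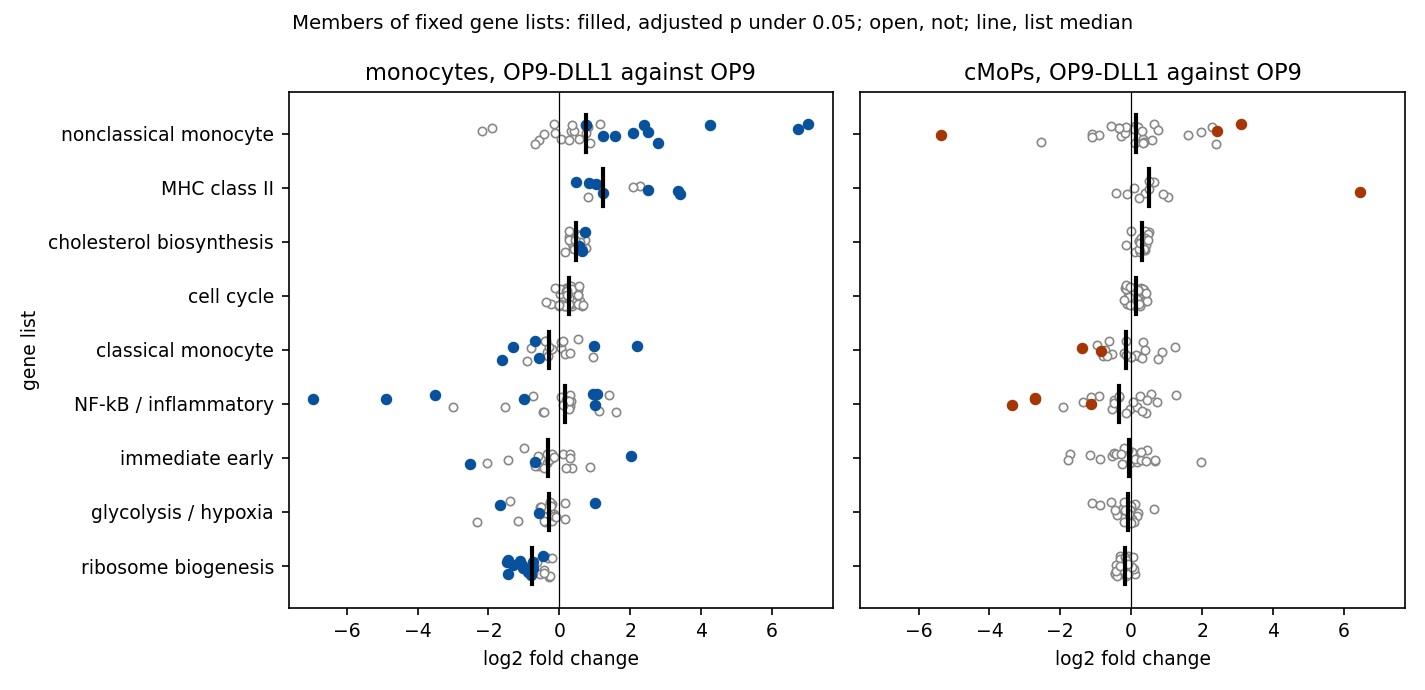
Log2 fold changes on OP9-DLL1 against OP9 of the members of 9 fixed gene lists, in monocytes (left) and cMoPs (right), filled where they passed, with a line at the list median. The ribosome biogenesis median is -0.76 in monocytes and -0.18 in cMoPs, and the class II median 1.22 and 0.50.

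On OP9, cMoPs differed from monocytes in the granule proteases and peroxidase of myeloid progenitors. Mpo, myeloperoxidase (chromosome 11, 87793581 to 87804413), was at 3902 ± 439 CPM in cMoPs and 12.4 ± 11.2 CPM in monocytes (SD, n = 2, log2 8.66 ± 0.53), and neutrophil elastase Elane at 8501 ± 1375 and 122 ± 29.0 CPM (6.13 ± 0.18). Ctsg (7.46 ± 0.44), Prtn3 (5.10 ± 0.30), Prss57 (8.67 ± 0.81), Ms4a3 (7.83 ± 0.24) and Nkg7 (7.20 ± 0.30) were higher in cMoPs as well, as were Sh2d5 (8.71 ± 0.64), Tuba8 (8.43 ± 1.06), the gluconeogenic enzyme Fbp1 (7.68 ± 1.03), Enpp4 (7.47 ± 1.27) and Tctex1d1 (7.45 ± 1.15). Lower in cMoPs were the interleukin gene Il1b (-8.46 ± 0.64), Pla2g7 (-8.19 ± 0.25), the scavenger receptor Cd36 (-8.11 ± 1.14), the chemokine Cxcl3 (-10.70 ± 1.23), Cbr2 (-8.52 ± 0.83), Oas2 (-7.82 ± 1.59), Serpinb2 (at least 345-fold, not without OP9 monocyte replicate 2, adjusted p at most 0.0604), Prr5l (at least 218-fold), Ppbp (0 reads in cMoPs, at least 2960-fold) and Ciita (0 reads, at least 259-fold). Bcl6 (-3.05 ± 0.60), Irf2 (-2.02 ± 0.16), Notch1 (-1.84 ± 0.18), Notch2 (-0.87 ± 0.16) and Nr4a1 (-4.69 ± 0.41) were lower and Ly6c2 (1.10 ± 0.16) higher in cMoPs, with limma-trend adjusted p from 8.9e-06 to 0.0021.

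Of 21 progenitor genes 16 were higher and 2 lower in cMoPs on OP9, and 27 of 38 cell cycle genes were higher, including the replication helicase subunits Mcm7 (log2 3.21 ± 0.14) and Mcm2 (3.47 ± 0.16), with 0 lower (limma-trend, 1 at an unadjusted p under 0.05, 0 by both voom fits). All 25 ribosome biogenesis genes were higher, with Nop56 at 2.41 ± 0.12 and Npm1 at 2.60 ± 0.15. Of 21 classical monocyte genes 17 were lower, among them Fn1 (-6.06 ± 0.16) and Vcan (-5.04 ± 0.20), and 4 higher, and of the nonclassical list 15 of 28 were lower and 4 higher. Of 26 interferon genes 21 were lower, of 24 NF-kB genes 20, of 29 transcription factors 19, with Id2 at -3.99 ± 0.12, of 22 immediate early genes 16, with Fos at -3.51 ± 0.15, and of 15 macrophage genes 11. Camera called 15 lists here, with adjusted p = 2.6e-06 for progenitor, 6.9e-08 for cell cycle and 1.7e-13 for ribosome genes. With an estimated correlation these had adjusted p = 0.19, 0.36 and 0.088. Classical (camera adjusted p = 4.4e-06, but adjusted p = 0.16 with an estimated correlation), nonclassical (0.0066 and 0.19), interferon (8.2e-08 and 0.16), NF-kB (7.7e-08 and 0.19), transcription factor (5.5e-05 and 0.17), immediate early (4e-06 and 0.088), macrophage (5.1e-05 and 0.12) and stroma genes (0.014 and 0.36) stood lower. With an estimated correlation none of the 20 lists passed (5 at an unadjusted p under 0.05), while fry called 15. Behind the small counts, and apart from Ly6c2 and Plac8 chosen for naming after their values were seen, were Cd93 (-0.64 ± 0.15) and Igsf6 (-0.57 ± 0.13) among progenitor genes. Among classical genes they included Ly6c2, Ly6c1 (1.26 ± 0.25) and Plac8 (2.57 ± 0.10). Among nonclassical genes they were Cx3cr1 (2.24 ± 0.30), Spn (2.16 ± 0.22), Lair1 (1.40 ± 0.13) and Slc12a2 (1.54 ± 0.48, not without OP9 monocyte replicate 2 or either cMoP library, adjusted p at most 0.13). Of 22 glycolysis and hypoxia genes 10 were higher and 5 lower, with Pgam1 at 0.86 ± 0.11 and Ankrd37 (-3.58 ± 0.33), Bnip3 (-1.21 ± 0.18), Pkm (-0.98 ± 0.13), Aldoa (-0.82 ± 0.13) and Eno1 (-0.80 ± 0.11) as those lower. Of 20 cholesterol genes 5 were higher and 3 lower, with Acat2, Dhcr7 (1.64 ± 0.20), Lss (1.32 ± 0.16), Fdps (0.85 ± 0.22) and Mvk (0.64 ± 0.16) higher and Mvd (-0.48 ± 0.14) and Srebf2 (-0.36 ± 0.12) among those lower. Mvk, Mvd and Srebf2 lost the call without cMoP OP9 replicate 1 (adjusted p at most 0.0625, 0.0909 and 0.154). Stroma genes were lower in cMoPs too, 8 of 13, which include Acta2 (-4.48 ± 0.27) and Thbs1 (-3.60 ± 0.33).

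On OP9-DLL1 the same contrast gave Mpo at 4838 ± 621 CPM in cMoPs and 16.5 ± 2.96 CPM in monocytes (log2 8.21 ± 0.53), Elane at 6.25 ± 0.18 and Nkg7 at 7.78 ± 0.30. The stem cell factor receptor Kit (7.08 ± 1.26), Nr0b2 (7.84 ± 0.62), Fkbp11 (7.55 ± 0.78), Prss57 (7.72 ± 0.81), Ctsg (7.15 ± 0.44), Enpp4 (7.26 ± 1.27), Slc43a1 (6.95 ± 0.41) and Fbp1 (at least 300-fold) were higher too. Spic was lower in cMoPs (-3.49 ± 0.32), as were H2-Ab1 (-5.67 ± 0.37), Cd74 (-6.59 ± 0.29), Flrt3 (-9.70 ± 0.67), the formyl peptide receptor Fpr1 (-9.17 ± 1.59) and Il1b (-8.62 ± 0.64). Genes with 0 reads in cMoPs were Pltp, Scel, Ppbp, Marco, Snai1 and Cxcl3, at least 317, 316, 260, 225, 210 and 191-fold lower. Marco lost the call without OP9-DLL1 monocyte replicate 1 (adjusted p at most 0.075). Bcl6 (-4.49 ± 0.60), Irf2 (-2.07 ± 0.16), Notch1 (-1.78 ± 0.18), Notch2 (-1.19 ± 0.16) and Nr4a1 (-3.60 ± 0.41) were lower and Ly6c2 (1.03 ± 0.16) higher. Hes1 was lower in cMoPs (-1.93 ± 0.58, limma-trend adjusted p = 0.018), a call that ended without any 1 of the 4 libraries (adjusted p at most 0.13). That standard error came from the spread of all 8 libraries, including OP9 libraries with few Hes1 reads. In the authors' deposited table Hes1 was at -1.92 in this contrast, with adjusted p = 6.9e-06. Of 25 ribosome biogenesis genes 25 were higher. Of 38 cell cycle genes 23 were higher and 2 lower, Cenpf (-0.97 ± 0.32) and E2f1 (-0.83 ± 0.21). Of 28 nonclassical genes 20 were lower and 4 higher, Cx3cr1 (2.31 ± 0.30), Spn (1.45 ± 0.22), Slc12a2 (1.41 ± 0.48) and Lair1 (0.50 ± 0.13). Cenpf, E2f1, Slc12a2 and Lair1 lost the call without OP9-DLL1 monocyte replicate 1 (adjusted p at most 0.129, 0.0652, 0.122 and 0.0816). These 6 were chosen for naming after their values were seen. Camera called 12 lists and none passed with an estimated correlation (6 at an unadjusted p under 0.05). Camera's adjusted p was 2.1e-15 for ribosome, 1e-06 for cell cycle and 0.00026 for nonclassical genes, against adjusted p = 0.09, 0.42 and 0.14 with an estimated correlation, while fry called 16.

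**Figure D4:**
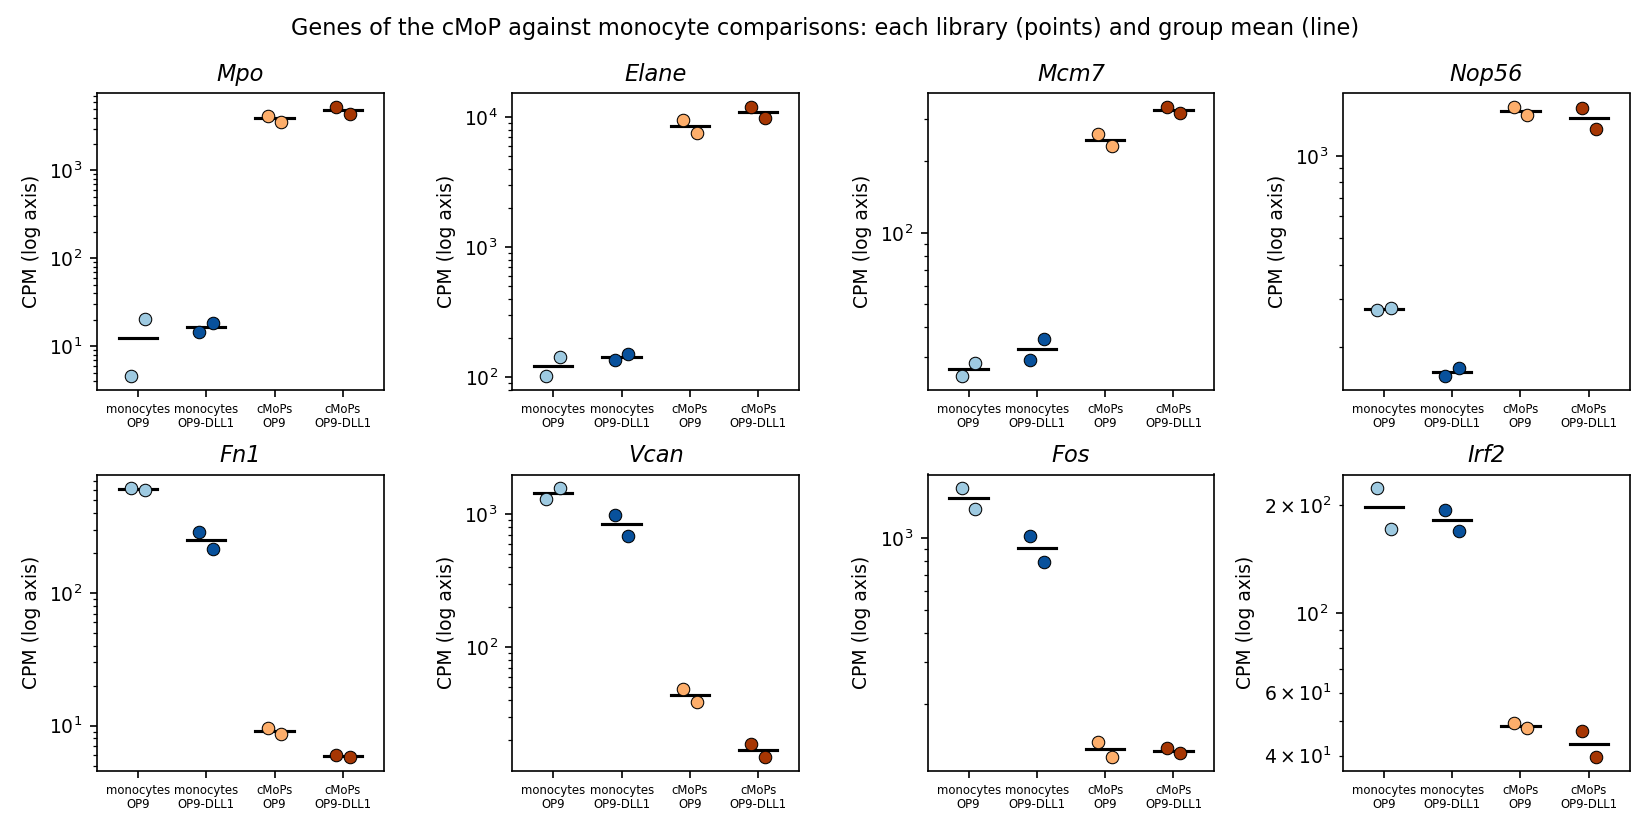
CPM (log axis) of 8 genes in each of the 8 libraries (points) with the group mean (line). Mpo, Elane, Mcm7 and Nop56 stand higher in all 4 cMoP libraries than in all 4 monocyte libraries, and Fn1, Vcan, Fos and Irf2 lower.

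In all, 7550 genes passed between cMoPs and monocytes on OP9, 3851 higher and 3699 lower in cMoPs, and 7671 on OP9-DLL1, 3768 higher and 3903 lower. Counts in the authors' deposited table were 6613 and 8668, with 6551 and 7665 shared in the same direction. Centring moved the median log2 fold change of all genes on OP9-DLL1 from -0.01 to 0.098, and changes there are to be read relative to such a shift.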

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

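The tests of explanations in this part, with 5 CPM added and without either OP9 monocyte library, were chosen only after the results were seen. 7 genes stand out because their response to OP9-DLL1 differed between cMoPs and monocytes in a direct test of the difference. The log2 differences, cMoPs minus monocytes, were 4.19 as fitted for Spic (2.60 with the cMoP fold taken over the floor of 3 counts, since cMoPs on OP9 had 0 reads), 3.23 for Pla2g7, 1.54 for Gpatch4, 1.34 for Hmga1, -1.78 for Plac8, -1.92 for Il21r and -2.33 for Pecam1.

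Spic started from 0 reads in cMoPs on OP9 and from 1.73 CPM in monocytes. Its fitted difference of 4.19 turned to -2.57 with 5 CPM added to every value. The added 5 CPM by itself limits the fold of a gene that starts from 0 reads. This turn therefore cannot decide whether a low starting level accounts for the difference. The other 6 genes kept direction and call with 5 CPM added, with differences of 2.136 for Pla2g7, 1.302 for Gpatch4, 1.267 for Hmga1, -1.76 for Plac8, -1.638 for Il21r and -1.751 for Pecam1. That setting by itself raised the count for this contrast to 60 genes, so the kept calls are weak evidence. The kept directions show only that 5 CPM did not turn these 6 differences, and a low starting level is not excluded for them. Whether the spread between the OP9 monocyte libraries contributed stays open, because all 7 kept direction and call without either of them, but leaving out 1 removes the largest spread and raised the count to 29 and 1123 genes. A difference between the cell types stays open beside it as an untested hypothesis for the 6, limited by the finding that none of the 7 passed without any 1 of the other 6 libraries (adjusted p at most 0.367 for Spic, 0.202 for Pla2g7, 0.28 for Gpatch4, Hmga1 and Il21r, and 0.12 for Pecam1 and Plac8).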

How the results depend on the processing

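Voom and weighted voom, and the replicate block for the correlation, were chosen only after the data had been seen. The planned count model on recovered reads was not run, and limma without the trend took its place. The count of genes responding to OP9-DLL1 in monocytes moved from 855 to 248 without the trend, 306 with only the 4 libraries compared, 405 with a log2 fold change of at least 1 and 536 by weighted voom, and ranged from 162 to 2482 with 1 library left out. In cMoPs it moved from 103 to 37 without the trend, 315 with only 4 libraries, 64 by voom and 268 by weighted voom, with 31 to 49 when 1 library was left out. The difference of responses moved from 7 genes to 1 without the trend and 60 with 5 CPM added, and from 0 to 1123 with 1 library left out (limma-trend, 787 to 3352 genes at an unadjusted p under 0.05). Spic's difference there was -2.571 with 5 CPM added, the only named result to change direction. A minimum log2 fold change of 1 left 4649 and 4880 genes between the cell types on OP9 and OP9-DLL1. With the correlation estimated per list, 0 lists were called in each of the 4 comparisons (4, 0, 5 and 6 at an unadjusted p under 0.05), against 7, 9, 15 and 12 by camera. Fry called 2 in cMoPs on OP9-DLL1, and camera 5 to 7 there with 1 library left out. Those 2 lists by fry were Notch targets and macrophage genes, both higher (fry adjusted p = 0.039 each). Of them 0 were among the 9 lists that camera called. For Notch targets in cMoPs camera gave a fall (adjusted p = 0.12), so both tests differ in sign. Why the counts moved was not tested, except that the left-out fits hold fewer samples and assume that a lone library varies like the other groups.

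The labels do not say whether same-numbered libraries belong together, and their deviations correlated at only 0.02 to 0.09. The replicate block gave 156 genes in place of 103 in cMoPs and 11 in place of 7 for the difference of responses. It moved no other count by more than 1.5 times, but raised every gene count. In monocytes it gave 1058 genes in place of 855. Between the cell types it gave 7674 in place of 7550 on OP9 and 7897 in place of 7671 on OP9-DLL1. Pdpn in monocytes (adjusted p = 0.0509) and Snai1 in cMoPs (adjusted p = 0.054) did not pass in it, while Car2 in monocytes (0.0403) and Nr4a1 (0.0334), Igsf6 (0.0349) and Cxcr2 (0.0272) in cMoPs did. The correlation of responses stayed positive, from 0.312 to 0.579. Of the named genes that passed, 27 of 59 in monocytes, 12 of 25 in cMoPs, 91 of 99 and 87 of 96 between the cell types on OP9 and OP9-DLL1, and 0 of 7 for the difference of responses passed under every setting. Depth limits the lowest genes: 3 reads correspond to 0.0453 to 0.0693 CPM, so folds of Hes1 in monocytes and Spic in cMoPs on OP9 are bounded by counting.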

Other observations

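All tests of explanations in this part were chosen only after the results were seen. Several lists differed between libraries of the same group. In monocytes on OP9 the median log2 CPM in replicate 1 and 2 was 5.28 and 6.11 for cell cycle, 1.23 and 2.46 for progenitor and 5.48 and 6.65 for class II genes, and on OP9-DLL1 it was 4.22 and 5.67 for neutrophil genes. In cMoPs on OP9 it was 3.66 and 4.79 for neutrophil, 2.44 and 1.51 for nonclassical and 1.72 and 1.06 for interferon genes. Mitochondrially encoded transcripts made up 0.56% and 0.90% of CPM in the OP9 monocyte libraries and 0.82% to 1.17% in the other 6.

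35 of 38 cell cycle genes were lower in OP9 monocyte replicate 1 than in replicate 2, with a median log2 difference of -0.93, against 0.10, 0.01 and -0.08 between the libraries of the other groups. 16 of 21 progenitor genes were lower in replicate 1 too, but progenitors carried over into replicate 2 are argued against as the source of the cell cycle difference, because the progenitor list would need a median of 0.958% of cMoP RNA and its granule genes Mpo, Elane, Prtn3, Ctsg and Ms4a3 0.49%, while the cell cycle genes would need 41.8%. A small carry-over is not excluded. Gene length is argued against too, because the median stayed at -0.98 relative to genes of like exonic length, although the difference had a rank correlation with length of -0.01 over all genes and -0.14 over the 7289 with a mean above 10 CPM. No biological explanation was tested.

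405 genes fell in monocytes on OP9-DLL1, where 11 stroma genes summed to 7.40 and 26.6 CPM against 44.6 and 39.4 CPM on OP9, none of them passing as lower and the list not called (camera adjusted p = 0.054, but adjusted p = 0.67 with an estimated correlation), and RNA of stromal cells carried over with the monocytes could contribute to that fall. The tables give no clear answer, and the form of the test reported as deciding was settled after other forms had been considered and their values seen. By that form, 186 of the 405 genes (45.9%) fell by more CPM than 11 stroma genes together, whose summed fall was 25 CPM, while the median fall of the 405 was 20.5 CPM. By a more lenient form 303 fell by more than any single stroma gene, of which Serpinh1 fell most, by 7.60 CPM, and by another the ratio of Ccl2 to summed stroma CPM was 37.9 and 27.6 on OP9 and 7.69 and 1.39 on OP9-DLL1 in monocytes, and 36.0 and 15.4 on OP9 and 2.87 and 3.68 on OP9-DLL1 in cMoPs, where Ccl2 and Spp1 fell while summed stroma was 3.92 and 6.98 CPM on OP9 and 7.26 and 4.65 CPM on OP9-DLL1. Carried-over stroma and a response of the monocytes cannot be told apart for these genes as a set, since OP9 and OP9-DLL1 cells were not measured alone here.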
